A study of Homo sapiens with 24 samples.

How the data were processed

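Total RNA of A2780 cells, a human ovarian cancer line, had been labelled with biotin and hybridised to 24 Affymetrix HT-HG_U133A Early Access arrays, 12 of cells transfected with the empty vector pcDNA and 12 of cells expressing Rab25. Per the labels, cells were starved of serum for 8 h and then given EGF (10 ng/ml), IGF (10 ng/ml), TGF beta (5 ng/ml) or fetal bovine serum (FBS, 5%). Each line had 4 serum-starved arrays and 2 arrays for each of the 4 treatments, split evenly over experiment 1 and experiment 2, which gave 10 groups. The treatment protocol gives an exposure of 8 h in experiment 1 and 24 h in experiment 2, whereas the source names give the same exposure in both experiments, and neither says how long the starved controls were kept beside the treated cells. The values were compared within and between experiments without settling that conflict.

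The authors deposited log2 expression values per probe set, with array distributions close to one another but not identical. The labels name MAS5 and RMA as processing tools, with no version, role or order, so background correction, summary and normalization are not known step by step. The arrays held 22930 probe sets, of which 524 were controls. A single gene symbol was given for 19415 probe sets, several symbols for 125 and none for 2866, and the probe set of highest mean over the 24 arrays stood for each of 11940 genes. The 2991 non-control probe sets without a single symbol were fitted apart.

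Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The design held the 10 groups and the experiment as a term, since every group had arrays in both experiments and the experiment deviations of the 45 pairs of groups correlated over genes at a median r of 0.66 (lowest 0.09, highest 0.86). The residual degrees of freedom were 13 and the prior degrees of freedom 3.51. Contrasts compared the mean of the 5 Rab25 groups with the mean of the 5 pcDNA groups, the starved groups of the lines, each treatment with starved cells over both lines, and the response to each treatment between the lines. A further fit with treatment by experiment terms compared the responses of the experiments by limma's moderated F and by each term. Adjusted p values are Benjamini-Hochberg values over all genes of a contrast, and 0.05 was the threshold. Errors of log2 fold changes are limma's standard errors (SE), and SD is given for groups of arrays.

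A set of 39 gene lists with 1072 genes, of which 960 were measured, was tested in each contrast with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Estimated correlation was the alternative and fry was run beside it. Counts of list members are given over all genes and adjusted over the list alone. Of the 57 list calls over all contrasts, 2 held with an estimated correlation, the TGF-beta and SMAD targets with TGF beta and the blood cell markers in the difference between lines in the FBS response.

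The contrasts, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took RAB25, the 12 largest rises and 12 largest falls between lines among called genes with 1 sign in all 10 condition by experiment cells, the 8 largest rises and falls of each treatment with 1 sign in all 4 line by experiment cells, up to 3 rises and 3 falls of each difference between lines, the 4 genes of lowest p in the F test, and up to 4 members of lowest p of each list described. Lists of breast epithelium (16 genes), adipocyte (9 genes) and macrophage (10 genes) markers were added after the data were seen.

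The fit was tested on simulated data of the same 11940 genes, with true log2 changes of 0.5, 1 and 2. It recovered 100% of genes at all 3 sizes for the lines over all conditions, and 73.1%, 95.5% and 100% for the starved lines. At a true log2 change of 1 it recovered 98.5% for EGF, IGF and FBS and 100% for TGF beta, but for the 4 differences between lines it recovered 22.4% to 37.3% at 0.5 and 79.1% to 86.6% at 1, and for the F test between experiments 4.48% and 59.7%. False calls were 1.38% to 7.02% of the calls. In the FBS comparison camera called the 1 list that had been moved and 0 of the 39 others in the simulated data. Genes were drawn independently of one another there, so this does not test the calls for lists of correlated genes.

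Alternatives were a fit without the experiment term, quantile normalization, centring of each array on its median, array quality weights, a trend with a robust prior, the median of a gene's probe sets, leaving out the lowest 40% of genes by mean, a 2-fold minimum, the groups compared alone, each experiment alone, and leaving out each array in turn. Treatment by experiment terms, the set without both Rab25 FBS arrays and the set without the 2 arrays of lowest median were added after the data were seen. RNA quality was read from the 3' minus 5' signal of the actin and GAPDH control probe sets and compared by 2-sided permutation tests, chosen after the data were seen. These used 100000 permutations within experiments or lines and all 9216 exchanges of matched arrays. Because the values are log signals without counts, the number of arrays limits the precision.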

Results

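Gene expression was measured on 24 HT-HG_U133A arrays of A2780 ovarian cancer cells that carried the empty vector pcDNA or expressed Rab25, a small GTPase of the Rab11 family that acts in endosome recycling. Each line had 4 serum-starved arrays and 2 arrays each with EGF, IGF, TGF beta and FBS, and each group was spread over 2 experiments. Array medians ran from 7.03 to 7.35 on the log2 scale. Starved arrays of the same line and experiment differed by an SD over genes of 0.144 to 0.173, and arrays of the same group in different experiments by 0.308 to 0.432. The first principal component held 38.9% of the variance and the second 17.0%. Each line was 1 transfected line, so differences between the lines include anything else that set these lines apart.

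**Figure D1:**
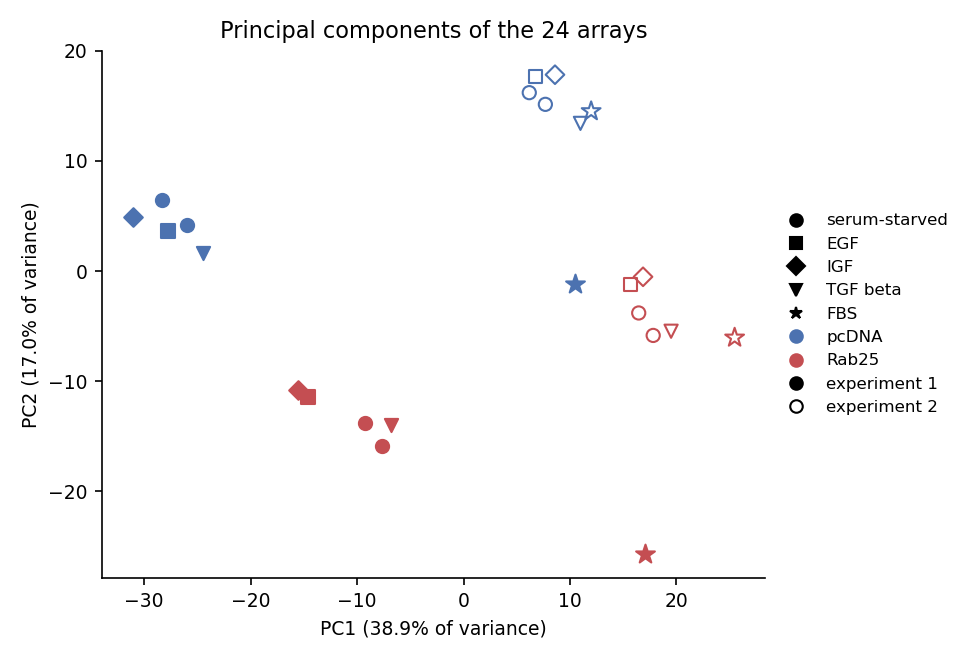
First and second principal components of the 24 arrays (each axis with its share of the variance), with colour for the line, filled symbols for experiment 1, open symbols for experiment 2 and a shape per condition. The lines part on the second component within each experiment, the starved, EGF, IGF and TGF beta arrays of experiment 1 lie below 0 on the first component, and the FBS arrays of both experiments lie above 0 on it.

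RAB25 was 10.1-fold higher in Rab25 than in pcDNA cells (1 probe set, log2 fold change 3.33, SE 0.09, limma adjusted p = 2.0e-13). Its mean signal was 5.26 ± 0.25 (SD, n = 12) in pcDNA and 8.65 ± 0.30 (SD, n = 12) in Rab25 cells, and it was higher in all 10 condition by experiment cells. In starved cells alone the log2 difference was 3.63 (SE 0.15). None of the treatments moved it past the threshold. The pcDNA signal lay near that of the liver genes ALB (5.01) and AFP (5.35) on these arrays, so the fold was taken against a signal near background.

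**Figure D2:**
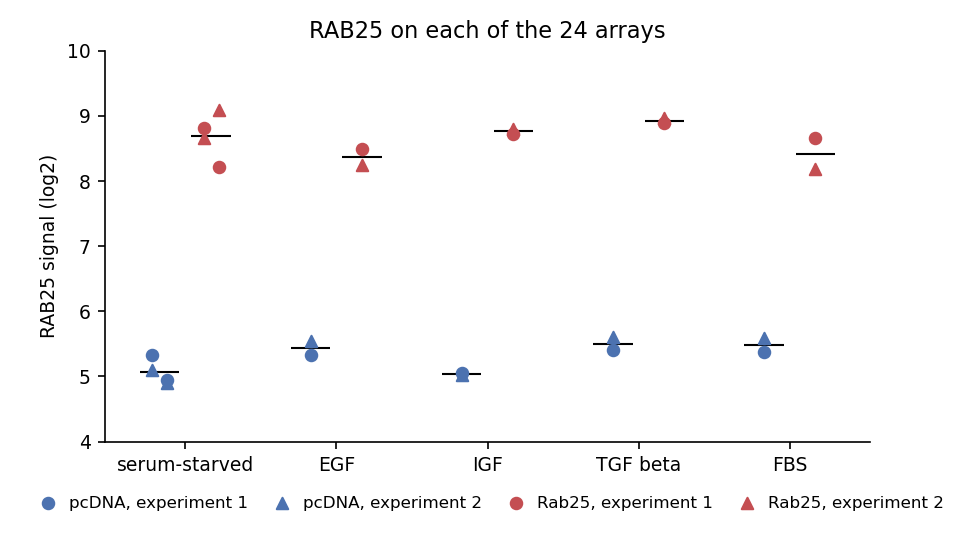
RAB25 signal (log2) on each array by condition, with circles for experiment 1, triangles for experiment 2 and a bar at the mean of each group. The 12 Rab25 arrays lie between 8.18 and 9.08, above all 12 pcDNA arrays, which lie between 4.90 and 5.60.

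The comparison of the lines over all conditions asked which transcripts differ in cells that express Rab25. After RAB25 itself, the largest rise was that of FKBP1B, an FK506-binding regulator of calcium release channels, at 9.30-fold (log2 3.22, SE 0.12). The cell cycle gene CCND2 was 4.16-fold higher (log2 2.06, SE 0.19) and the immediate-early transcription factor EGR1 3.51-fold higher (log2 1.81, SE 0.17). The desmosome gene DSP was 2.94-fold higher, CPT1A, which brings fatty acids into mitochondria, 2.73-fold, and the lipid carrier PLTP 2.62-fold. NMU, AJAP1, CLIC3, GPR4 and COL1A1 completed the 12 named rises, at log2 1.47, 1.38, 1.38, 1.36 and 1.51. In the other direction PNMA2 was 6.28-fold lower (log2 -2.65, SE 0.10), the collagen gene COL5A1 5.28-fold lower (log2 -2.40, SE 0.14), the protease inhibitor LXN 4.68-fold lower (log2 -2.23, SE 0.21) and the membrane glycoprotein CDCP1 4.65-fold lower (log2 -2.22, SE 0.04). The Notch target HES1 had a log2 change of -1.75 and the growth factor TGFB2 of -1.72. LRIG1, which restrains EGF receptor signalling, was at -1.37. TNFSF15, SLC12A8, SEL1L3, SCG5 and VIPR1 had log2 changes of -1.98, -1.83, -1.70, -1.39 and -1.33. Some of the changes were taken against a signal near background, such as LXN in Rab25 cells (mean 5.34) and GPR4 in pcDNA cells (mean 5.15).

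By limma, 2944 of 11940 genes differed between the lines, 1091 higher and 1853 lower in Rab25 cells, and 1714 of them had 1 sign in all 10 cells of condition and experiment. A change of at least 2-fold was found for 60 genes, 25 higher and 35 lower. The majority of lower genes rested on the scaling, since quantile normalization gave 1429 higher and 1473 lower and centring on array medians 1514 higher and 1258 lower. Without the experiment term 1665 genes passed. The actin 3' minus 5' signal, a sign of RNA quality, was lower in Rab25 arrays in 8 of 10 matched sets (exact permutation p = 0.0399). Other probe sets of CCND2, COL1A1 and HES1 gave -0.02, -0.02 and 0.03, and those of FKBP1B, EGR1, CPT1A and TGFB2 ran down to 0.06, 0.11, 0.00 and -0.05. The CPT1A call was lost with the median of its probe sets. Without the Rab25 FBS arrays the COL1A1 change was 0.99 (SE 0.23) in place of 1.51.

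Among the gene lists, 15 of the 35 ATF4 and amino acid response genes were lower in Rab25 cells and 0 higher (adjusted over the list alone, 18 lower). CBS, of cysteine synthesis, fell by 0.93 (SE 0.10), the lipoprotein receptor gene VLDLR by 1.03 (SE 0.11), the stress factor NUPR1 by 1.20 (SE 0.19) and VEGFA by 0.54 (SE 0.09) on the log2 scale. The camera adjusted p of this list was 3.6e-05, and with an estimated correlation it was 0.736. Of 16 replication-dependent histone genes, 9 were lower (adjusted over the list alone, 10), among them H1-2 at -0.51 and H2AC6 at -0.59 (camera adjusted p = 0.00848). Of 20 heat shock genes, 9 were lower and 1, STIP1, higher (adjusted over the list alone, 12 and 2), with HSPB1 at -0.31 and HSPH1 at -0.29 (camera adjusted p = 0.0169). Of 15 HLA class I and antigen presentation genes, 7 were lower (adjusted over the list alone, 8), among them ERAP1 at -0.41 and HLA-B at -0.18 (camera adjusted p = 0.0259). Of 29 hypoxia genes, 12 were lower and 2 higher (adjusted over the list alone, 13 and 2), with NDRG1 at -0.93 and the glucose transporters SLC2A3 at -1.10 and SLC2A1 at -0.49 (camera adjusted p = 0.0288). Of 22 genes of the unfolded protein response, 3 were lower (adjusted over the list alone, 3), PDIA3 at -0.31, SERP1 at -0.29 and HERPUD1 at -0.50 (camera adjusted p = 0.0313). The WNT and beta-catenin list had 7 of 16 genes higher and 2 lower (adjusted over the list alone, 7 and 2), with CCND2 above, LEF1 at 0.49 and DKK3 at 0.28, against the receptor FZD7 at -0.72 (camera adjusted p = 0.0288). With an estimated correlation the adjusted p of the histone, heat shock, HLA, hypoxia and WNT lists was 0.736 each and that of the unfolded protein response 0.820. The WNT call was also lost with either other scaling. It was lost without 4 of the 24 arrays in turn, the unfolded protein response call without 8 and the hypoxia call without 5.

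Several lists fixed for Rab25 biology moved both ways. Of 28 genes of the Rab11 family and recycling endosome, 8 were higher and 7 lower (adjusted over the list alone, 8 and 7), with CLIC3 at 1.38, the motor gene MYO5C at 0.93 and EHD3 at 0.69 against RAB7A at -0.30 (camera adjusted p = 0.430). Of 18 integrin genes, 5 were lower and 1 higher (adjusted over the list alone, 5 and 1), with ITGB3 at -0.61, ITGA2 at -0.51, ITGB5 at -0.49 and ITGA5 at -0.30 (camera adjusted p = 0.217). Of 25 epithelial junction and keratin genes, 6 were higher and 3 lower (camera adjusted p = 0.0816; adjusted over the list alone, 6 and 3), with SPINT2 at 0.74 beside DSP. Among 29 mesenchymal genes, 3 were higher and 6 lower (camera adjusted p = 0.719; adjusted over the list alone, 3 and 6), where FN1 was at 0.51 and TNC at 0.62 against ZEB2 at -0.76.

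In serum-starved cells, without any added growth factor, the genes named between the lines had the same sign, which the naming rule required. FKBP1B was higher by log2 3.61 (SE 0.20) and CCND2 by 2.02 (SE 0.31), while PNMA2 was at -2.66 (SE 0.16), COL5A1 at -2.52 (SE 0.24) and CDCP1 at -2.17 (SE 0.06). EGR1 was at 0.84 (SE 0.28) and COL1A1 at 1.03 (SE 0.37), neither past the threshold (limma adjusted p = 0.0536 and 0.0722). Of the ATF4 list, 10 of 35 genes were lower (adjusted over the list alone, 15), with NUPR1 at -1.51 and VLDLR at -1.11 (camera adjusted p = 9.94e-07, and 0.876 with an estimated correlation). Of 20 heat shock genes, 5 were lower and 1 higher (adjusted over the list alone, 9 and 1), with HSPH1 at -0.37 and DNAJB4 at -0.74 (camera adjusted p = 0.00883, and 0.876 with an estimated correlation). By limma 1767 genes differed, 664 higher and 1103 lower, and 72 at least 2-fold. The split was 950 higher and 865 lower after quantile normalization and 744 and 770 after median centring. The count was 730 without the experiment term, 3273 with array weights, 3056 from the 8 starved arrays alone and 2884 with treatment by experiment terms.

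The EGF comparison asked which genes respond to EGF over both lines. No single gene passed the threshold: limma called 0 genes, with 811 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0849, for the potassium channel gene KCNJ2 (log2 -0.68, SE 0.11, chosen for mention after its value was seen). Adjusted over the list alone, 6 of 35 ATF4 genes rose, with CHAC1 at 0.96 (SE 0.17), DDIT4 at 0.77 (SE 0.23) and MARS1 at 0.22 (SE 0.06), none of which passed over all genes. The camera adjusted p of that list was 2.52e-14, and 0.365 with an estimated correlation. The ribosome biogenesis list had a median of 0.11 (camera adjusted p = 9.33e-11, and 0.157 with an estimated correlation), with BYSL at 0.24 and DDX21 at 0.22. The NF-kB list had a median of 0.21 and 3 of 27 members past the threshold adjusted over the list alone (camera adjusted p = 1.14e-07, and 0.181 with an estimated correlation), with IL1B at 0.29, ICAM1 at 0.37 and IL1A at 0.35. The ERK-induced list had a median of 0.10 (camera adjusted p = 2.72e-05, and 0.157 with an estimated correlation), with EGR1 at 0.79 (SE 0.24). The mean EGR1 signal was 5.86 in starved and 5.94 in EGF-treated pcDNA cells, against 6.70 and 8.19 in Rab25 cells. Its rise thus lay mostly in Rab25 cells, although the difference between the lines did not pass the threshold. The FOXO and growth factor withdrawal list had a median of -0.11 and 5 of 36 lower adjusted over the list alone, with IRS2 at -0.46 and CITED2 at -0.30 (camera adjusted p = 1.04e-04, and 0.365 with an estimated correlation). Camera also called the endothelial list (median -0.09, adjusted p = 0.00249, and 0.365 with an estimated correlation) and glycolysis (median 0.04, adjusted p = 0.0323, and 0.878 with an estimated correlation), the latter lost with either other scaling and without 5 of the 24 arrays in turn. The count of genes by limma was 40 with array weights, 59 from the 12 arrays compared alone, 106 with treatment by experiment terms, 2 with either other scaling, 4 in experiment 1 alone and 95 in experiment 2 alone. It was 4 without either pcDNA FBS array and 1 without either pcDNA IGF array.

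Named genes that passed with IGF included genes of amino acid metabolism and cell growth among the rises and a chemokine receptor among the falls. CHAC1, which degrades glutathione, rose 2.86-fold (log2 1.51, SE 0.17, limma adjusted p = 6.57e-04) and DDIT4, an inhibitor of the growth kinase mTORC1, rose 2.14-fold (log2 1.09, SE 0.23). TAGLN, UPP1, SYBU, EFNB2, the serine synthesis gene PSAT1 and TIMP4 rose by log2 0.95, 0.92, 0.85, 0.83, 0.83 and 0.70. The chemokine receptor gene CXCR4 fell 4.39-fold (log2 -2.13, SE 0.33, limma adjusted p = 0.0034). ADAMTS5, SIGLEC15, HBP1, PTCH1, KCNJ2, DKK1 and RGCC fell by 0.93, 0.91, 0.89, 0.88, 0.86, 0.86 and 0.84 on the log2 scale. The naming rule required these 16 genes to move 1 way in all 4 cells of line and experiment. Even so, the fall of SIGLEC15 was -1.56 in experiment 1 and -0.25 in experiment 2 and that of HBP1 -0.25 and -1.53. Another probe set of PTCH1 gave 0.02. The HBP1 call was lost without 17 of the 24 arrays in turn, that of ADAMTS5 without 13, PSAT1 without 8, SIGLEC15 without 6, RGCC without 5, DDIT4 and TAGLN without 3 each, UPP1, TIMP4 and DKK1 without 2 each and EFNB2 and PTCH1 without 1 each.

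Of 35 ATF4 genes 6 rose with IGF and 0 fell (adjusted over the list alone, 21 rose), with the transporter gene SLC7A5 at 0.67 and MARS1 at 0.33 (camera adjusted p = 5.32e-16, and 0.438 with an estimated correlation). Of 36 ribosome biogenesis and MYC targets 8 rose (adjusted over the list alone, 20), with DDX21 at 0.41, NOP2 at 0.44, BYSL at 0.39 and DKC1 at 0.29 (camera adjusted p = 4.59e-15, and 0.102 with an estimated correlation). Of 36 FOXO and withdrawal genes 11 fell and 1 rose (adjusted over the list alone, 18 and 2), with IRS2 at -0.84, IGF1R at -0.59, CITED2 at -0.56 and PIK3IP1 at -0.51 (camera adjusted p = 2.23e-08, and 0.241 with an estimated correlation). Of 27 NF-kB genes 2 rose, IL1A at 0.47 and TNFAIP3 at 0.45 (adjusted over the list alone, 8; camera adjusted p = 2.96e-06, and 0.328 with an estimated correlation). The remaining called lists had camera adjusted p values of 0.01 to 0.0328 and lost the call with an estimated correlation (adjusted p = 0.438 to 0.779) or without the first IGF array of either line. They were heat shock and glycolysis with positive medians, and extracellular matrix, endothelial, mesenchymal and embryonic patterning genes with negative ones, the last with SOX17 at -0.76 (SE 0.07). By limma 323 genes responded to IGF, 140 up and 183 down, of which 321 had 1 sign in all 4 cells and 3 changed at least 2-fold. The count fell to 10 without the experiment term, to 52 without Rab25 IGF replicate 1, 88 without pcDNA IGF replicate 1, 183 and 201 without pcDNA starved replicates 2-1 and 1-1 and 214 without Rab25 starved replicate 1-2. It was 515 without either Rab25 FBS array or both. It was 796 with array weights, 885 from the arrays compared alone, 1298 with treatment by experiment terms, 853 in experiment 1 alone and 549 without the 2 arrays of lowest median.

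Several known targets passed with TGF beta. NEDD9, a scaffold protein of cell migration, rose 5.20-fold (log2 2.38, SE 0.29), the WNT regulator DACT1 4.21-fold (log2 2.07, SE 0.22), PMEPA1, which restrains SMAD signalling, 4.19-fold (log2 2.07, SE 0.16, limma adjusted p = 3.69e-06) and the fibroblast protease gene FAP 3.77-fold (log2 1.92, SE 0.25). The oxidase gene NOX4, the actin-binding gene TAGLN, the transcription factor SOX4 and the basement membrane collagen COL4A1 rose by log2 1.69, 1.63, 1.61 and 1.56. FGFBP1, PTX3, KCNJ2 and THBD fell by 1.25, 1.13, 1.13 and 1.02, and RGCC, ADM, VIPR1 and CSF3 by 0.92, 0.89, 0.87 and 0.86 on the log2 scale. All 16 had 1 sign in the 4 cells of line and experiment, as the naming rule required. The rise of DACT1 was 1.37 in experiment 1 and 2.78 in experiment 2 (difference 1.42, SE 0.20, limma adjusted p = 0.00499) and that of SOX4 1.15 and 2.07 (difference 0.92, SE 0.11, limma adjusted p = 0.00259). The VIPR1 call was lost without 8 of the 24 arrays in turn, those of FGFBP1 and RGCC without 2 each and those of THBD and ADM without 1 each.

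Of 35 TGF-beta and SMAD targets 12 rose and 0 fell (adjusted over the list alone, 15 rose), with LTBP2 at 0.64 and TGFBI at 1.29 beside NEDD9 and PMEPA1. The camera adjusted p was 3.89e-18, and the call held with an estimated correlation at an adjusted p of 0.00562. Of 46 extracellular matrix genes 4 rose, COL4A1, COL4A2 at 1.09, COL5A1 at 1.07 and SERPINE2 at 0.88 (adjusted over the list alone, 5); the median of the list was -0.01 and its mean 0.12, and the camera adjusted p of 0.0223 was lost with either other scaling and was 0.980 with an estimated correlation. Of 23 SRF and actin genes 2 rose, TAGLN and TPM1 at 0.29 (adjusted over the list alone, 3; camera adjusted p = 0.00677, and 0.980 with an estimated correlation). The ribosome biogenesis list had 0 called members and a median of 0.06 (camera adjusted p = 0.00691, and 0.980 with an estimated correlation). Its medians were -0.017 in experiment 1 and 0.125 in experiment 2 (camera adjusted p of the difference 0.0156, and 0.948 with an estimated correlation). Its call was lost without 2 of the 24 arrays in turn, that of the extracellular matrix list without 3 and that of the SRF list without 1, and the ribosome biogenesis mean fell from 0.05 to 0.01 without Rab25 TGF beta replicate 2. Of 25 epithelial junction genes 0 passed by limma in either direction, over all genes or adjusted over the list alone (camera adjusted p = 0.559), with CDS1 at 0.57 (SE 0.16). By limma 191 genes responded, 101 up and 90 down, 189 with 1 sign in all 4 cells, 20 at least 2-fold up and 4 at least 2-fold down. The split was 122 up and 72 down after quantile normalization and 134 and 44 after median centring. The count was 55 without the experiment term, 55 without pcDNA TGF beta replicate 2, 127 without Rab25 TGF beta replicate 2, 380 from the arrays compared alone, 498 with treatment by experiment terms, 89 in experiment 1 alone and 431 in experiment 2 alone.

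In the FBS comparison ID1, a BMP-responsive inhibitor of differentiation factors, rose 9.83-fold (log2 3.30, SE 0.20, limma adjusted p = 8.9e-08) and ID3 6.70-fold (log2 2.74, SE 0.29), both larger in experiment 2 (4.01 and 3.78) than in experiment 1 (2.58 and 1.71). RGS2 rose 2.43-fold (log2 1.28, SE 0.17). The cystine transporter gene SLC7A11 fell 8.40-fold (log2 -3.07, SE 0.39), the stress transcription factor ATF3 5.20-fold (log2 -2.38, SE 0.35) and the asparagine synthetase ASNS 4.74-fold (log2 -2.25, SE 0.31). CHAC1, TRIB3, DDIT3, DDIT4 and STC2 fell by 1.95, 1.95, 1.89, 1.81 and 1.71 on the log2 scale, where DDIT3 was at -1.14 (still called) without pcDNA FBS replicate 1. POSTN, MGP, FABP4, COL1A1 and SCGB2A2 also passed, at log2 2.33, 1.98, 1.68, 1.62 and 1.55, but they rose in the Rab25 FBS arrays, and without Rab25 FBS replicate 1 POSTN was at 1.36 and MGP at 0.82. In pcDNA cells alone, fitted without the Rab25 FBS arrays, their changes were 0.26, 0.10, 0.11, 0.34 and 0.04, not past the threshold, while ID1 (3.40), ID3, RGS2 (0.95) and the 8 named falls were still called.

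Of 35 ATF4 genes 32 fell with FBS and 0 rose (adjusted over the list alone, 35 fell), with SLC38A2 at -1.01 and ATF4 itself at -0.75 (camera adjusted p = 1.26e-25, and 0.193 with an estimated correlation). The fall was larger in experiment 1 (median -1.29) than in experiment 2 (median -0.49). Of 36 ribosome biogenesis genes 21 rose (adjusted over the list alone, 22), with NOP16 at 0.55 and NOP56 at 0.47 (camera adjusted p = 3.67e-14, and 0.108 with an estimated correlation). Of 36 G1/S genes 16 rose (adjusted over the list alone, 26), with CHAF1B at 0.68, CCNE1 at 0.57 and FEN1 at 0.42 (camera adjusted p = 7.57e-14, and 0.378 with an estimated correlation). Of 44 G2/M genes 3 rose, CDC20 at 0.63, ESPL1 at 0.57 and CKS2 at 0.54 (adjusted over the list alone, 1; camera adjusted p = 2.1e-07, and 0.612 with an estimated correlation). The medians of the G1/S and G2/M lists were 0.83 and 0.85 in experiment 1 against 0.01 and -0.11 in experiment 2 (camera adjusted p of the difference 4.12e-14 and 2.64e-11, and 0.235 and 0.551 with an estimated correlation). Without Rab25 FBS replicate 1 the means of these lists fell from 0.45 and 0.33 to 0.27 and 0.06. The cholesterol synthesis list likewise had a median of -1.11 in experiment 1 and 0.10 in experiment 2 (camera adjusted p of the difference 1.3e-16, and 0.175 with an estimated correlation), with 5 of 21 genes called lower over both (adjusted over the list alone, 13), among them SREBF2 at -0.69 and CYP51A1 at -0.99 (camera adjusted p = 5.06e-04, and 0.594 with an estimated correlation). The unfolded protein response list, with 4 of 22 lower (adjusted over the list alone, 8), had medians of -0.60 and 0.04 (camera adjusted p of the difference 2.22e-17, and 0.172 with an estimated correlation), with DNAJB9 at -1.44 and HERPUD1 at -1.13 (camera adjusted p = 6.96e-05, and 0.529 with an estimated correlation). In starved cells the medians of experiment 2 minus experiment 1 were 0.97 for G1/S, 0.72 for G2/M, -0.75 for unfolded protein response and -0.56 for ATF4 genes. Part of the difference between experiments in these lists thus lay in the starved controls. The cholesterol list shifted by 0.22 there, which works against its difference. The FBS calls of the cholesterol, unfolded protein response, FOXO, heat shock, NF-kB and epithelial lists were each lost without 2 of the 24 arrays in turn, and that of the p53 list without 1.

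Of 29 hypoxia genes 15 fell and 2 rose (adjusted over the list alone, 16 and 2), with KDM3A at -0.82 (camera adjusted p = 6.96e-05, and 0.235 with an estimated correlation). Of 33 ERK-induced and immediate-early genes 13 fell and 1, JUN at 0.49, rose (adjusted over the list alone, 15 and 1), with KLF4 at -1.09 and ETV5 at -0.37 (camera adjusted p = 0.00272, and 0.235 with an estimated correlation). Of 36 FOXO and withdrawal genes 11 fell and 2 rose (adjusted over the list alone, 12 and 2), with BTG1 at -1.12, CITED2 at -1.09 and the cell cycle inhibitor CDKN1B at -0.87 (camera adjusted p = 0.00395, and 0.492 with an estimated correlation). Of 24 p53 targets 11 fell and 1 rose (adjusted over the list alone, 11 and 2), with PMAIP1 at -1.10 (camera adjusted p = 0.00395, and 0.494 with an estimated correlation). Of 27 NF-kB genes 9 fell (adjusted over the list alone, 12), with CXCL2 at -1.15 and IRF1 at -0.82 (camera adjusted p = 0.0134, and 0.494 with an estimated correlation). Of 46 nuclear-encoded oxidative phosphorylation genes 8 rose (adjusted over the list alone, 8), with ATP5MC1 at 0.51 (camera adjusted p = 1.21e-08, and 0.492 with an estimated correlation). Heat shock genes rose in 6 of 20 and fell in 2 (adjusted over the list alone, 8 and 2), with HSPE1 at 0.38 and DNAJB4 at -0.62 (camera adjusted p = 0.00348, and 0.366 with an estimated correlation). Of 23 SRF and actin genes 4 rose (adjusted over the list alone, 4), with TAGLN at 1.12 and MYL9 at 0.54 (camera adjusted p = 0.00731, and 0.494 with an estimated correlation). In pcDNA cells alone 0 SRF and actin genes rose by limma and neither this list nor heat shock was called (camera adjusted p = 0.168 and 0.172). In experiments 1 and 2 the medians were 0.22 and 0.00 for oxidative phosphorylation, 0.00 and -0.28 for FOXO and withdrawal, -0.47 and -0.13 for hypoxia, -0.41 and -0.10 for p53, -0.01 and 0.16 for heat shock and -0.31 and -0.12 for NF-kB genes. The difference between the experiments was called by camera for the first 4 (adjusted p = 1.08e-07, 0.00334, 3.98e-04 and 5.72e-04), but not with an estimated correlation (adjusted p = 0.175, 0.483, 0.184 and 0.509). It was not called for heat shock and NF-kB (camera adjusted p = 0.194 and 0.079).

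The fibroblast, blood cell, extracellular matrix, mesenchymal and epithelial lists were also called up with FBS (camera adjusted p = 1.64e-05, 0.00343, 7.13e-06, 0.00348 and 0.0294), with estimated-correlation adjusted p values of 0.213, 0.108, 0.378, 0.492 and 0.494. In pcDNA cells alone the fibroblast, blood, mesenchymal and epithelial lists were not called (camera adjusted p = 0.714, 0.714, 0.116 and 0.717). The extracellular matrix list was still called up there (median 0.18, camera adjusted p = 0.0182, and 0.666 with an estimated correlation), with 1 of 46 genes up and 2 down. Its median in pcDNA cells was 0.30 in experiment 1 and 0.02 in experiment 2.

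By limma 2057 genes responded to FBS, 768 up and 1289 down, 1529 with 1 sign in all 4 cells, 21 at least 2-fold up and 47 at least 2-fold down. The split was 979 up and 1089 down after quantile normalization and 1032 and 851 after median centring. Without both Rab25 FBS arrays 1243 genes responded in pcDNA cells, of which 1009 were called in the same direction among the 2057. The count was 396 without the experiment term, 367 with array weights, 3358 with treatment by experiment terms, 3678 in experiment 1 alone and 1176 in experiment 2 alone. It was 757, 1246 and 3181 without pcDNA FBS replicate 1, Rab25 FBS replicate 1 and Rab25 FBS replicate 2.

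**Figure D3:**
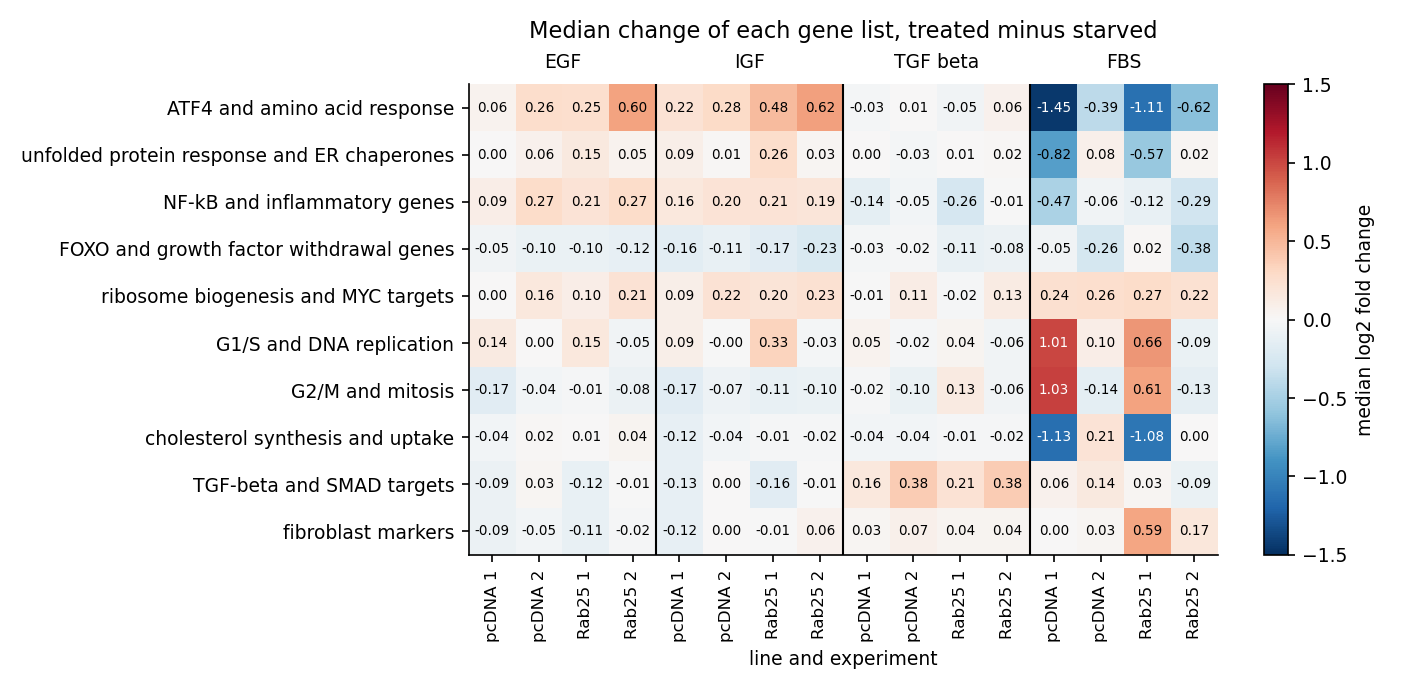
Median log2 fold change (colour and printed value) of 10 gene lists, treated minus starved cells of the same line and experiment, for the 4 treatments, 2 lines and experiments 1 and 2. The ATF4 list is above 0 in the 4 IGF columns and below 0 in the 4 FBS columns, and the G1/S list with FBS is at 1.01 and 0.66 in experiment 1 against 0.10 and -0.09 in experiment 2.

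Differences between the lines in the response to a treatment would show dependence on Rab25 or on anything else that set the lines apart. For FBS, the collagen genes COL3A1 and COL1A2 and the matrix gene LUM rose in Rab25 but not in pcDNA cells, with differences of log2 6.91 (SE 0.51), 4.65 (SE 0.50) and 4.27 (SE 0.61) and limma adjusted p values of 1.54e-06, 1.66e-04 and 0.0041. On the 22 arrays other than Rab25 FBS, COL3A1 and LUM averaged 5.32 and 4.71, so their differences were taken against a signal near background. Without Rab25 FBS replicate 1 the LUM difference was 2.81. The COL3A1 response was 7.51 and 5.83 in the Rab25 arrays and -0.43 and -0.04 in the pcDNA arrays of experiments 1 and 2, although another of its probe sets gave a difference of -0.24. In the other direction SOX17, an endoderm transcription factor, had responses of -1.37 and -1.29 in Rab25 and of -0.27 and 0.03 in pcDNA cells (difference -1.21, SE 0.15, limma adjusted p = 6.26e-04). The replication gene GINS4 was at 2.08 and 1.45 in pcDNA cells against -0.21 and -1.51 in Rab25 cells (difference -2.62, SE 0.51), and the polarity gene LLGL1 at 0.80 and 0.46 against -0.48 and -0.37 (difference -1.06, SE 0.21), with limma adjusted p values of 0.0428 and 0.0444. The GINS4 and LLGL1 calls were lost without 15 and 20 of the 24 arrays in turn.

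By limma 25 genes differed in their FBS response, 17 with a positive and 8 with a negative difference of Rab25 minus pcDNA responses, and 16 at least 2-fold. The positive calls included the macrophage markers CD74 and C1QB and the breast marker SCGB2A2, at 5.68, 5.085 and 5.54 on the 22 arrays other than Rab25 FBS. They also included SMC5 and STXBP3, at 9.30 and 11.1. Whether RNA of other human cells contributed to these calls stayed open, as set out below. The fibroblast list had 4 of 14 genes up and the blood list 2 of 15, TYROBP at 1.76 and HBB at 0.63 (adjusted over the list alone, 5 and 6; camera adjusted p = 4.07e-09 and 4.12e-06, and 0.0629 and 0.00601 with an estimated correlation). The extracellular matrix list had 3 of 46 genes up (adjusted over the list alone, 4), with a median of -0.01 and a mean of 0.45 (camera adjusted p = 0.0356, and 0.978 with an estimated correlation). The epithelial list had a median of 0.19 and the G1/S list of -0.31 with 0 called members by limma over all genes or adjusted over the list alone (camera adjusted p = 0.0219 each, and 0.978 each with an estimated correlation). Without Rab25 FBS replicate 1 the mean of the epithelial list went from 0.34 to 0.01, and over both lines its mean with FBS went from 0.16 to -0.01. The mean of the G1/S list changed sign without Rab25 FBS replicate 2 and without pcDNA FBS replicate 1. The extracellular matrix, G1/S and epithelial calls were lost without 8, 5 and 3 of the 24 arrays in turn. The split was 34 up and 7 down after quantile normalization and 28 and 4 after median centring. The count was 82 with treatment by experiment terms, 11 with array weights, 6 from the arrays compared alone, and 3 without the lowest 40% of genes. It was 202 without Rab25 FBS replicate 1, 191 without Rab25 FBS replicate 2, 198 without the 2 arrays of lowest median and 16 without pcDNA starved replicate 2-1.

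**Figure D4:**
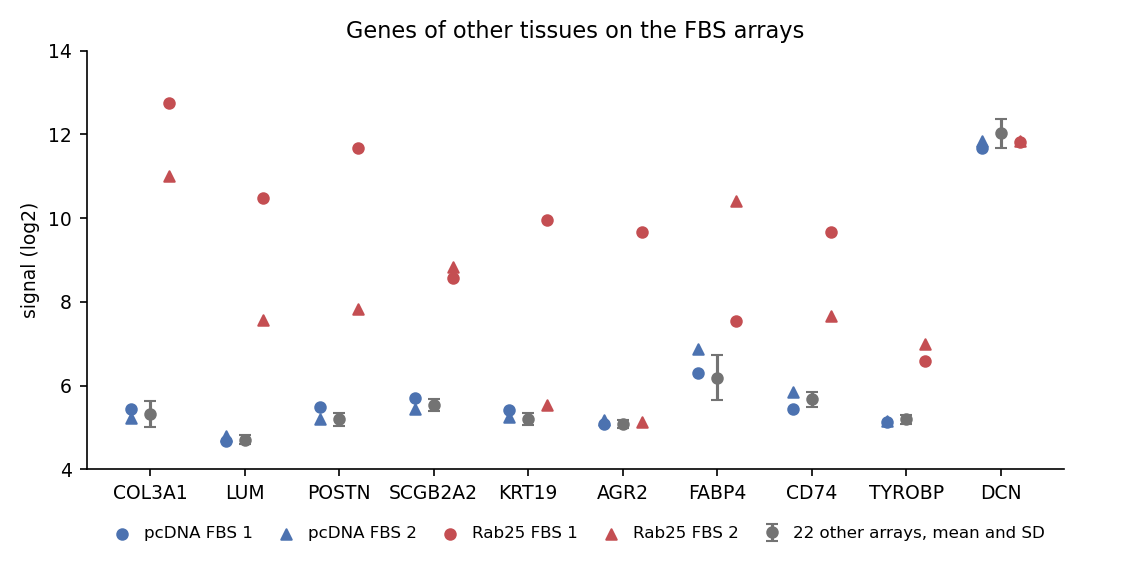
Signal (log2) of 10 genes, chosen for display after their values were seen, on the pcDNA FBS (blue) and Rab25 FBS (red) arrays of experiment 1 (circles) and experiment 2 (triangles), with grey points and bars for the mean and SD of the 22 arrays other than Rab25 FBS. LUM lies at 10.5 and 7.57 on the Rab25 FBS arrays against 4.71 elsewhere, KRT19 at 9.95 and 5.54 against 5.20, and DCN at 11.8 and 11.8 against 12.0.

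For the other treatments limma called 0 genes in the difference between lines, with 415, 253 and 622 genes at an unadjusted p under 0.05 for EGF, IGF and TGF beta. Leaving out single arrays gave 1 gene for EGF (without Rab25 starved replicate 2-2), 1 for IGF (without either pcDNA FBS array) and 17 for TGF beta (without Rab25 TGF beta replicate 2), and array weights gave 1 for IGF. The ATF4 list was called with larger changes in Rab25 cells, at a median difference of 0.23 for EGF and 0.29 for IGF (camera adjusted p = 0.0153 and 4.54e-05, and 0.981 and 0.993 with an estimated correlation), and the EGF call was lost without 6 of the 24 arrays in turn. CHAC1 differed by 0.51 (SE 0.34) and 0.63 (SE 0.34), neither past the threshold. The embryonic patterning list was called lower for IGF (median -0.06, camera adjusted p = 0.0107, and 0.683 with an estimated correlation), with SOX17 at -0.87 (SE 0.15, limma adjusted p = 0.254), and the call was lost without 2 of the 24 arrays in turn.

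The experiments were set side by side because the labels disagree on their exposure times. In starved cells 33 of 36 G1/S and 42 of 44 G2/M genes were higher in experiment 2 than in experiment 1 (medians 0.97 and 0.72), while 19 of 22 genes of the unfolded protein response, 26 of 35 ATF4 genes and 17 of 27 NF-kB genes were lower (medians -0.75, -0.56 and -0.56). Camera called all 5 lists (adjusted p = 4.2e-25, 4.6e-13, 1.31e-16, 6.98e-10 and 9.85e-09), and with an estimated correlation their adjusted p values were 0.113, 0.491, 0.0906, 0.376 and 0.306. By limma 3741 genes differed between the experiments in starved cells, 1763 higher and 1978 lower in experiment 2, or 2127 and 1589 after median centring.

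By limma's F test 2013 genes passed for a difference between the experiments in the responses, a count that 5 of 100 splits of the samples reached, the real one included. Chance was not excluded for it by these splits, but they cannot decide it. They exchange the experiments within single groups, which turns the shift shared by the groups into differences between responses. The neuroendocrine gene SCG5 changed with FBS by -2.62 in experiment 1 and 0.30 in experiment 2, the ERK phosphatase DUSP5 by -2.24 and -0.62, the chaperone HYOU1 by -1.63 and 0.26 and the cholesterol synthesis gene MSMO1 by -1.62 and 0.12 (SE of each difference 0.13, 0.09, 0.10 and 0.09; limma adjusted p of the F test 1.14e-06, 1.51e-06, 1.7e-06 and 2.49e-06). In starved cells these genes changed by -1.05, -0.67, -1.63 and 0.09 in experiment 2 relative to experiment 1. Part of the first 3 differences in response thus lay in the starved controls. The FBS response differed for 2682 genes, 1138 up and 1544 down in experiment 2 relative to experiment 1, or 1494 and 1381 after quantile normalization and 1674 and 885 after median centring. The IGF, TGF beta and EGF responses differed for 169, 48 and 10 genes. Without either Rab25 FBS array 1530 genes differed in the FBS response and 1112 by the F test, and without the 2 arrays of lowest median 1638 and 1037.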

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

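The tests of the 3 patterns below were chosen after the results were seen, and 2 of their criteria, on exposure time and on a response that depends on Rab25, were changed or withdrawn after their values were known. Differences between the lines or between the experiments were picked up by limma or camera tests of the difference itself, single arrays by their gap to the nearest array of their group, and probe sets without a single gene symbol because no comparison of genes used them.

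The FBS response differed between the lines for 25 genes, with COL3A1 at 6.91, COL1A2 at 4.65, LUM at 4.27, GINS4 at -2.62, SOX17 at -1.21 and LLGL1 at -1.06 on the log2 scale. By camera the fibroblast (adjusted p = 4.07e-09), blood cell (4.12e-06), extracellular matrix (0.0356), epithelial (0.0219) and G1/S (0.0219) lists differed too, but with an estimated correlation only the blood list kept its call (adjusted p = 0.0629, 0.00601, 0.978, 0.978 and 0.978). The ATF4 list differed between the lines for EGF (camera adjusted p = 0.0153) and IGF (4.54e-05), and the embryonic patterning list for IGF (0.0107), calls that were lost with an estimated correlation (adjusted p = 0.981, 0.993 and 0.683).

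On the Rab25 FBS array of experiment 1, 76 genes lay at least 2-fold above every array of the other groups, and on that of experiment 2 18 genes did, against 0 to 4 on the other arrays; of the 76, 34 (44.7%) were also above all of those arrays in replicate 2. RNA of other human cells on these arrays stayed open: the blood list differed with an adjusted p of 0.00601 with an estimated correlation, but that call was known when it was made the criterion, so it describes the pattern and does not test it. Serum was given to both lines, and the fibroblast median was 0.0147 in pcDNA FBS cells against 0.377 in Rab25 FBS cells. The pattern was picked for that difference, so these medians restate it and do not test the serum as a cause. After quantile normalization 41 genes were still called, so the calls did not rest on that scaling, although this criterion too was set after the result was seen. Breast tissue as the source stayed open, because the median rise of the breast list was 2.29 in replicate 1 but 0.11 in replicate 2, while of its genes SCGB2A2 was 3.01 and 3.11 and SCGB1D2 0.45 and 2.27 above starved Rab25 cells in replicates 1 and 2. A response to FBS that depends on Rab25 was not settled: a criterion that it would share at least 90% of the genes above between replicates was set after the result was seen and withdrawn after 44.7% was measured, so it is left open.

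Estimated-correlation adjusted p values over 8 marker lists, for the difference between lines in the FBS response, were 9.74e-04 for blood cell, 0.00861 for fibroblast, 0.690 for endothelial and 0.929 for keratinocyte and hepatocyte markers. The macrophage (9.74e-04), breast (0.0278) and adipocyte (0.0545) lists were added after the values were seen, so their p values describe the pattern and do not test it. The adjustment over the 8 lists included these added lists, so the adjusted p values of the other lists are no test either. Over the planned lists, as given above, the blood list kept its call with an estimated correlation and the fibroblast list did not. Medians in Rab25 FBS replicates 1 and 2 were 1.02 and 0.58 for macrophage, 0.27 and 0.11 for blood cell, 0.59 and 0.17 for fibroblast, -0.01 and 0.19 for adipocyte, -0.13 and -0.07 for endothelial, 0.06 and 0.02 for keratinocyte, and 0.00 and -0.12 for hepatocyte markers. Elsewhere 4 of 14 fibroblast, 2 of 15 blood cell, 3 of 11 endothelial, 2 of 12 keratinocyte, 1 of 14 hepatocyte, 4 of 16 breast, 0 of 9 adipocyte and 1 of 10 macrophage genes already lay above the array median. The fibroblast gene DCN was among those, at 12.0. The matrix genes SPARC and FN1, which were not on the fibroblast list, lay at 12.5 and 14.6. Such high signals would hide a small share of other cells. In Rab25 FBS replicates 1 and 2, 6 and 5 of 14 fibroblast genes rose by more than log2 1. So did 3 and 2 of 15 blood cell and 5 and 4 of 10 macrophage genes. Some markers of low signal elsewhere moved little there. PDGFRA was at 6.41 elsewhere against 6.22 and 6.36, MFAP4 at 5.58 against 5.50 and 5.66, and CD3D at 6.20 against 6.20 and 6.10.

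The experiments differed for 3741 genes in starved cells, and the responses differed between them for 2013 genes by the F test. Of 100 splits of the samples 5 reached that count, the real one included. Because these splits turn the shift shared by the groups into differences between responses, they leave chance undecided for it. Single terms gave 10 genes for EGF, 169 for IGF, 48 for TGF beta and 2682 for FBS. The FBS response of SCG5, DUSP5, HYOU1 and MSMO1 was 2.92, 1.62, 1.89 and 1.74 higher in experiment 2. Their starved controls changed by -1.05, -0.67, -1.63 and 0.09 in experiment 2 relative to experiment 1, so part of the first 3 differences lay there.

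A batch of array processing would shift all conditions alike, and over the 3741 genes the shift between experiments in pcDNA EGF, IGF and TGF beta arrays followed that of the starved arrays with slopes of 0.96, 1.02 and 0.96, but the FBS arrays with a slope of 0.107 in pcDNA and 0.41 in Rab25 cells. This argues against such a batch as the whole cause. With the actin 3' minus 5' signal as a covariate 3234 genes were called, of which 3021 were among the 3741 in the same direction. This argues against RNA quality only as far as that 1 control signal follows it. Other differences in RNA quality are left open. A first criterion, that exposure time would leave starved cells alike, spoke against exposure time with 3741 genes that differ, but it was reversed after that value was seen because the labels do not say how long the controls were kept. Exposure time therefore cannot be told apart from anything else that differed between the experiments.

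The ATF4 list moved up with IGF and down with FBS, and 3 explanations by the design were looked at. Error in the shared starved controls moves both changes the same way, so by design it could not give opposite changes. It would give a covariance of 0 or above between the changes over the 35 genes, and it was -0.133 (-0.130 and -0.138 with the controls split between the treatments, 0.0166 in simulated data). The covariance adds no test beyond the design. A single line or experiment is argued against by medians of opposite sign in 4 of 4 line by experiment cells, and the Rab25 FBS arrays by 31 of 35 genes lower and 0 higher with FBS in pcDNA cells alone (median -1.02, camera adjusted p = 4.74e-26, and 0.209 with an estimated correlation). A difference in amino acid demand and supply between IGF and FBS is a hypothesis only and was not tested.

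Among starved arrays, single values stood apart in 5 of 154 sets of 4, each a gene or an array measure in 1 line. A chance rate of about 1 in 20 holds for 4 values of 1 normal population. Each set here held arrays of both experiments, which differed for many genes, so that rate does not apply. The gap divided by the range was 0.898 for MGP and 0.952 for FABP4 on pcDNA starved replicate 1-2, 0.892 for COL3A1 on pcDNA starved replicate 1-1, 0.885 for GINS4 on pcDNA starved replicate 1-2 and 0.830 for PTX3 on Rab25 starved replicate 1-1. Of 2991 probe sets without a single gene symbol, 396 differed between the lines over all conditions and 240 responded to FBS.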

How the results depend on the processing

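The use of the fit with treatment by experiment terms for the comparisons of lines and treatments, and the fits without both Rab25 FBS arrays and without the 2 arrays of lowest median, were chosen after the results were seen, while the F test between experiments was planned. No named gene turned its direction under any setting. For the genes of the lines and treatments the naming rule required 1 sign in every cell, so fits to 1 experiment could not turn it. Of the 57 list calls in the contrasts of lines and treatments, 2 were left with an estimated correlation. The cause was not tested for the values below, except that a 2-fold minimum can only lower a count and that fits to 1 experiment or to the groups compared hold fewer arrays. Interactions could not be fitted within 1 experiment, the difference between lines for FBS could not be fitted without the Rab25 FBS arrays, a change of scale was not run because the values are log2 already, and array signals near background limit the genes of low mean.

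Counts of genes were as follows where a setting moved them. Without the replicate block given by the experiment, 1665 genes differed between the lines, 730 in starved cells, and 10, 55 and 396 responded to IGF, TGF beta and FBS; the block changed no other count by over 1.5 times. At least 2-fold changes were found for 60 genes between the lines, 72 in starved cells, 3 with IGF, 24 with TGF beta, 68 with FBS and 16 in the difference between lines for FBS. Array weights gave 3273 for the starved lines, 40 for EGF, 796 for IGF, 367 for FBS, 1 for the difference in the IGF response and 11 for that in the FBS response. The groups compared alone gave 3056 for the starved lines, 59 for EGF, 885 for IGF, 380 for TGF beta and 6 for the difference in the FBS response. Treatment by experiment terms gave 2884 for the starved lines, 106 for EGF, 1298 for IGF, 498 for TGF beta, 3358 for FBS and 82 for the difference in the FBS response. Quantile normalization gave 2 for EGF and 41 for the difference in the FBS response, and median centring 2 for EGF. Experiment 1 alone gave 4 for EGF, 853 for IGF, 89 for TGF beta and 3678 for FBS, and experiment 2 alone 95 for EGF, 431 for TGF beta and 1176 for FBS. Without both Rab25 FBS arrays 515 genes responded to IGF and 1243 to FBS. Without the 2 arrays of lowest median the counts were 549 for IGF, 3258 for FBS, 198 for the difference in the FBS response, 1638 for the FBS response between experiments and 1037 by the F test. Without the lowest 40% of genes by mean the difference in the FBS response held 3 genes.

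Leaving out each array in turn gave 2504 to 3366 genes between the lines, 1195 to 2145 in starved cells, 0 to 4 for EGF, 52 to 515 for IGF, 55 to 238 for TGF beta and 757 to 3181 for FBS. The differences between lines gave 0 to 1 for EGF, 0 to 1 for IGF, 0 to 17 for TGF beta and 16 to 202 for FBS. Between experiments the starved cells gave 3172 to 3876, the FBS response 1530 to 2712 and the F test 1112 to 2122, and 55 to 81 lists were called. A group left with 1 array was taken to vary like the others. In the difference between lines for FBS, the mean of the epithelial list turned to -0.0494 without the lowest 40% of genes. The mean of the G1/S list ran from -0.639 without Rab25 FBS replicate 1 to 0.0615 without Rab25 FBS replicate 2, and was 0.0604 without pcDNA FBS replicate 1. That of the extracellular matrix list ran from 0.143 without Rab25 FBS replicate 1 to 0.758 without Rab25 FBS replicate 2, and without pcDNA FBS replicate 2, at a mean of 0.293, camera turned its direction; the cause was not tested.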

Other observations

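The RNA quality tests that close this part were chosen after the data were seen, while the counts over regrouped samples and the gene lists were planned. Members of further lists differed between the lines, although camera called none of these lists. Of 16 BMP and ID genes 5 were lower in Rab25 cells and 0 higher (adjusted over the list alone, 5), among them the transcription factor HEY1 at -1.20 (SE 0.05), the BMP pseudoreceptor BAMBI at -1.04 and the inhibitor SMAD7 at -0.58 (camera adjusted p = 0.0816). Of 19 glycolysis genes 7 were lower and 1 higher (adjusted over the list alone, 8 and 1), with LDHB at -0.63 and TPI1 at -0.25 (camera adjusted p = 0.0546). Of 14 fatty acid synthesis genes 8 were lower and 2 higher (adjusted over the list alone, 10 and 2), with SCD at -0.70 and SREBF1 at -0.42 against FADS2 at 0.55 (camera adjusted p = 0.0816). Of 23 SRF and actin genes 7 were higher and 2 lower (adjusted over the list alone, 8 and 2), with TAGLN at 1.29, MYL9 at 0.64 and ACTA2 at 0.52 (camera adjusted p = 0.0816). The drug resistance list went both ways, 4 of 30 higher and 8 lower (adjusted over the list alone, 4 and 8), with GSTP1 at 0.47 and HMOX1 at -0.61 (camera adjusted p = 0.430).

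With FBS, 10 of 30 drug resistance and detoxification genes fell and 2 rose (adjusted over the list alone, 11 and 4), among them the metallothioneins MT1E at -0.76, MT1X at -0.57, MT1G at -0.40 and MT2A at -0.36 (camera adjusted p = 0.182). Of 21 YAP/TAZ targets 5 rose and 0 fell (adjusted over the list alone, 5), with FJX1 at 0.96 and CCN2 at 0.63 (camera adjusted p = 0.135). With TGF beta, 3 of 29 mesenchymal genes rose and 2 fell (adjusted over the list alone, 4 and 2), with FAP above and TWIST1 at -0.28 (camera adjusted p = 0.198).

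The samples were also regrouped at random, the real grouping counted among the splits. For the lines, 1 of 100 splits gave as many as 2944 genes (highest other 158), and 1 of 34 splits of the 8 starved arrays as many as 3056 (highest other 0). For the treatments, 12 arrays each were fitted with terms for line, experiment and treatment, whereas the fit to the groups compared alone kept a term for each group, so the counts differ. In this fit 1 of 100 splits gave as many genes for EGF (54, highest other 1), IGF (983, highest other 1), TGF beta (413, highest other 1) and FBS (1374, highest other 37). For the experiments in starved cells 1 of 34 splits gave as many as 3873 (highest other 0). All these gene counts passed the planned rule in these fits only, and the main fit called 0 genes for EGF. For the lines over all conditions the splits kept condition and experiment matched, and chance was excluded in that fit. The splits of the treated and of the starved arrays did not keep line and experiment balanced as the real grouping did. Starved arrays of 1 line and experiment were also close to one another, so single arrays were not free to exchange. Those splits therefore cannot exclude chance. The F test between experiments gave as many as 2013 genes in 5 of 100 splits, the highest other being 3464. Chance was not excluded there, but these splits cannot decide it. Exchanging the experiments within single groups turns the shift they share into differences between responses. For lists, the planned rule was passed, in these fits, for the starved lines (1 of 34 splits with as many as 10, highest other 9). The same held for IGF (3 of 100 with as many as 16, highest other 18) and FBS (1 of 100 with as many as 20, highest other 18). In the main fit 2, 10 and 19 lists were called there, and 0 of these held with an estimated correlation, so the splits say little of those calls. Chance was not excluded for the lists of the lines over all conditions (32 of 100 with as many as 7, highest other 13), EGF (6 of 100 with as many as 15, highest other 17) and TGF beta (26 of 100 with as many as 6, highest other 13).

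The 3' minus 5' signal of the actin control was 0.881 ± 0.148 (SD, n = 12) in pcDNA and 0.781 ± 0.119 (SD, n = 12) in Rab25 arrays (permutation within experiments, p = 0.0564), and 0.891 in experiment 1 against 0.771 in experiment 2 (permutation p = 0.0239). For GAPDH the permutation p values were 0.0963 between the lines and 0.112 between the experiments. With arrays matched by condition and experiment, actin was lower in Rab25 in 8 of 10 sets (exact permutation p = 0.0399) and GAPDH higher in 9 of 10 (exact permutation p = 0.0768). Matched by line and condition, the exact permutation p between experiments was 0.0213 for actin and 0.169 for GAPDH.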
